A study of Arabidopsis thaliana with 36 samples.

How the data were processed

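RNA was measured in 36 libraries from hypocotyls of 7-day-old Arabidopsis thaliana seedlings, in 12 groups of 3 biological replicates per the series design. The groups cross 4 genotypes with 3 tissues. The genotypes were Col-0 (wild type), a mutant labelled dof quadruple, and mutants labelled erf114,115 and anac071,096. The tissues were the uncut hypocotyl (intact), the hypocotyl above the graft junction (scion) and the hypocotyl below it (rootstock), the grafted ones taken 24 h after grafting. Per the labels' protocols, a piece of 1 mm was taken from intact plants and 0.5 mm on each side of the junction, RNA was purified with a ROTI Prep RNA MINI kit, and polyA RNA was made into paired-end libraries with a NEBNext Ultra RNA kit and 13 cycles of PCR.

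The deposited table holds raw counts per locus for the 36 libraries, as whole numbers. The authors trimmed reads with fastp, aligned them with HISAT2 to TAIR10, counted them with HTSeq and tested them with DESeq2, per the submitters' processing notes. The strand setting and the annotation release used for counting are not given in the sources used here. Reads of overlapping or antisense loci, and reads shared by near-identical paralogs such as the RBCS, LHCB, XTH and CASP families, could therefore not be assigned with certainty, and values of single members of such families are uncertain. All 36 columns were used, 0 were left out, and 0 rows named no locus. The table has 33341 loci, of which 33056 have a row in the reference annotation and 10804 a symbol there. Names and coordinates were taken from the TAIR10.1 reference annotation by locus identifier, and no coordinate was converted.

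Library totals were 19.5 to 30.5 M counts, with a median of 23.8 M (M being the SI prefix mega). Values in CPM (counts per M counts of the library) were computed on library sizes scaled by edgeR's TMM factors, which ran from 0.784 to 1.31. Intervals and floors cover counting error only, since PCR copies could not be recognised without molecular identifiers. A group listed at 0 was set to a floor of 3 counts summed over its 3 libraries, and folds against it are written as "at least". A group with 1 to 3 counts is given as a ratio of CPM with a 95% counting interval.

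Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, and robust quasi-likelihood tests in 1 fit of all 12 groups with 24 residual degrees of freedom. The filter left 19476 loci. Every adjusted p of a gene is from this quasi-likelihood test with Benjamini-Hochberg adjustment over these loci within a comparison, two-sided, and a gene passed at an adjusted p under 0.05. Log2 changes are given with their standard error (SE) and CPM with the standard deviation (SD) over 3 libraries. The 24 comparisons form 4 families: 3 between tissues of Col-0, 6 of graft tissues with intact tissue in the mutants, 9 of a mutant with Col-0 in the same tissue, and 6 of a mutant's grafting response with that of Col-0. "Rose" and "fell" are used of genes and lists that passed.

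The 22 gene lists hold 371 loci, all present in the table. The reference names 337 of them alike, and 34 were matched by locus alone. Apart from the 8 targeted genes, the lists were the other DOF family, wound and regeneration regulators, jasmonate, ethylene, auxin response, cytokinin response, cambium, xylem and secondary wall, phloem, DNA replication, mitosis, primary cell wall, photosynthesis, sugar starvation, sugar abundance, hypoxia, salicylate and defence, endodermis and suberin, epidermis and stomata, shoot meristem and root hair. Each list was tested against the other genes with limma 3.58.1 camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 63, 126, 189 and 126 list tests of the 4 families. It was tested again with the correlation estimated from the list itself, and with fry, which asks whether the list's genes move on balance 1 way without comparing them with other genes. A list's value is the median log2 change of its tested members, with a second value where members have a group at 0. Counts of passing members are also given adjusted over the list alone.

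Groups, comparisons, lists, the first alternatives and the rule for the genes named were fixed before the data were examined. The rule named the 8 targeted genes in every comparison, and up to 5 genes with the most positive and 5 with the most negative log2 change that passed. Those genes needed a symbol, a mean of at least 10 CPM in a compared group and, outside the response differences, every library of 1 group above every library of the other. It also named, for each list, up to 4 members with the smallest adjusted p, or the member with the highest mean where none passed. The labels name the dof mutant only as dof quadruple. That its lesions lie in HCA2, TMO6, DOF2.1 and DOF6 was taken from general knowledge of this line, not from the labels.

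The tests were run on simulated counts for the real genes and library sizes, with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. For Col-0 scion minus intact (19326 genes), 13.4%, 53.7% and 98.5% of the genes changed by these folds were recovered, with 6 false calls among 116. For dof quadruple minus Col-0 in the scion (19341 genes) the shares were 13.4%, 56.7% and 90.9%, with 6 false calls among 113. For the dof quadruple response minus the Col-0 response in the scion (19346 genes) they were 1.49%, 20.9% and 59.1%, with 6 false calls among 60.

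Replicate numbers are shared by all groups, and the labels do not say what a number stands for. For 30 compared pairs of groups, deviations of libraries with the same number from their group means were correlated. Every such correlation was over 0.1 in 7 pairs of groups, of which 5 are compared directly: dof quadruple minus Col-0 in the intact hypocotyl and the rootstock, erf114,115 minus Col-0 in the intact hypocotyl, and both erf114,115 responses. There the numbers were treated as pairing the libraries, from this check of the data alone. The fit without a replicate block is the main one throughout.

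The alternatives were RLE size factors, upper-quartile scaling, no low-count filter, a DESeq2 1.42.0 Wald test, limma-voom, a fit of the compared groups only, a replicate block, a 2-fold minimum, and leaving out each library in turn. Lists were also run with RLE, the block and no filter. Effects of the mutants were compared across genes by correlation and covariance, beside groups simulated without any effect, controls included (10 draws). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.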

Results

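Grafting cuts the hypocotyl of a seedling across and joins the shoot part of a plant to the root part of another, so that the cut ends must heal and reconnect their vascular strands. The libraries record RNA levels beside the junction after 24 h, in wild-type Col-0 and in 3 mutants of transcription factor genes, with uncut hypocotyls as the background. A cotyledon was removed from intact and grafted plants alike. The series concerns cell-wall damage, DOF factors and regeneration after wounding, and the comparisons ask which genes respond on each side of the junction and which of these responses differ in the mutants.

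The ranges of library totals of the 12 groups overlapped. Loci of the organelles took 0.5% to 2.49% of a library, and the 10 most counted loci took 5.4% to 10.9%. The first 2 principal components held 42.6% and 28.3% of the variance and the third 5.17%. The common coefficient of biological variation was 25.8%. Col-0 rootstock replicate 1 counted 2514 loci at 0 in the other 35 libraries, against at most 34 such loci in any other.

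The targeted genes were measured first. In dof quadruple, DOF6 (AT3G45610, chromosome 3) had 0 counts in the 3 intact libraries, 0 in the 3 scions and 1 in the 3 rootstocks. Col-0 had 1.08 ± 0.141, 2.19 ± 0.482 and 1.79 ± 0.351 CPM of DOF6 in these tissues (SD, n = 3). The other genes taken to be hit in this mutant were still counted. HCA2 (AT5G62940, chromosome 5) stood at 7.86 ± 0.757 CPM in intact tissue, 82.5 ± 8.83 in scions and 52.7 ± 6.31 in rootstocks, against 7.44 ± 0.945, 23.6 ± 3.11 and 39.5 ± 6.36 in Col-0. TMO6 (AT5G60200, chromosome 5) stood at 19.5 ± 0.362, 47.3 ± 7.62 and 75.5 ± 13.0 CPM, against 27.3 ± 3.04, 118.6 ± 2.24 and 209.9 ± 41.5. DOF2.1 (AT2G28510, chromosome 2) stood at 32.4 ± 5.27, 146 ± 7.21 and 147.9 ± 17.7 CPM, against 14.6 ± 4.22, 239.8 ± 9.32 and 411 ± 27.9. Reads from outside a lesion are still counted, so the levels of HCA2, TMO6 and DOF2.1 do not check this label, and of the 4 genes only DOF6 does.

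In erf114,115, ERF115 (AT5G07310, chromosome 5) had 0 counts in intact tissue, 0.882 ± 0.630 CPM in scions and 0.987 ± 0.635 in rootstocks. In Col-0 it had 0.0612, 63.9 ± 8.29 and 28.6 ± 1.28 CPM. ERF114 (AT5G61890, chromosome 5) had 0.0709, 6.87 ± 0.636 and 5.76 ± 0.320 CPM in this mutant and 0.152, 58.6 ± 8.05 and 64.3 ± 1.32 in Col-0. In anac071,096, ANAC071 (AT4G17980, chromosome 4) had 0 counts in intact tissue, 5.88 ± 2.1 CPM in scions and 2.14 ± 0.789 in rootstocks, against 0 counts, 23.7 ± 4.52 and 13.1 ± 3.92 CPM in Col-0. ANAC096 (AT5G46590, chromosome 5) had 0.13, 6.34 ± 0.908 and 6.09 ± 0.784 CPM in this mutant and 0.654, 33.2 ± 4.51 and 51.6 ± 2.39 in Col-0.

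**Figure D1:**
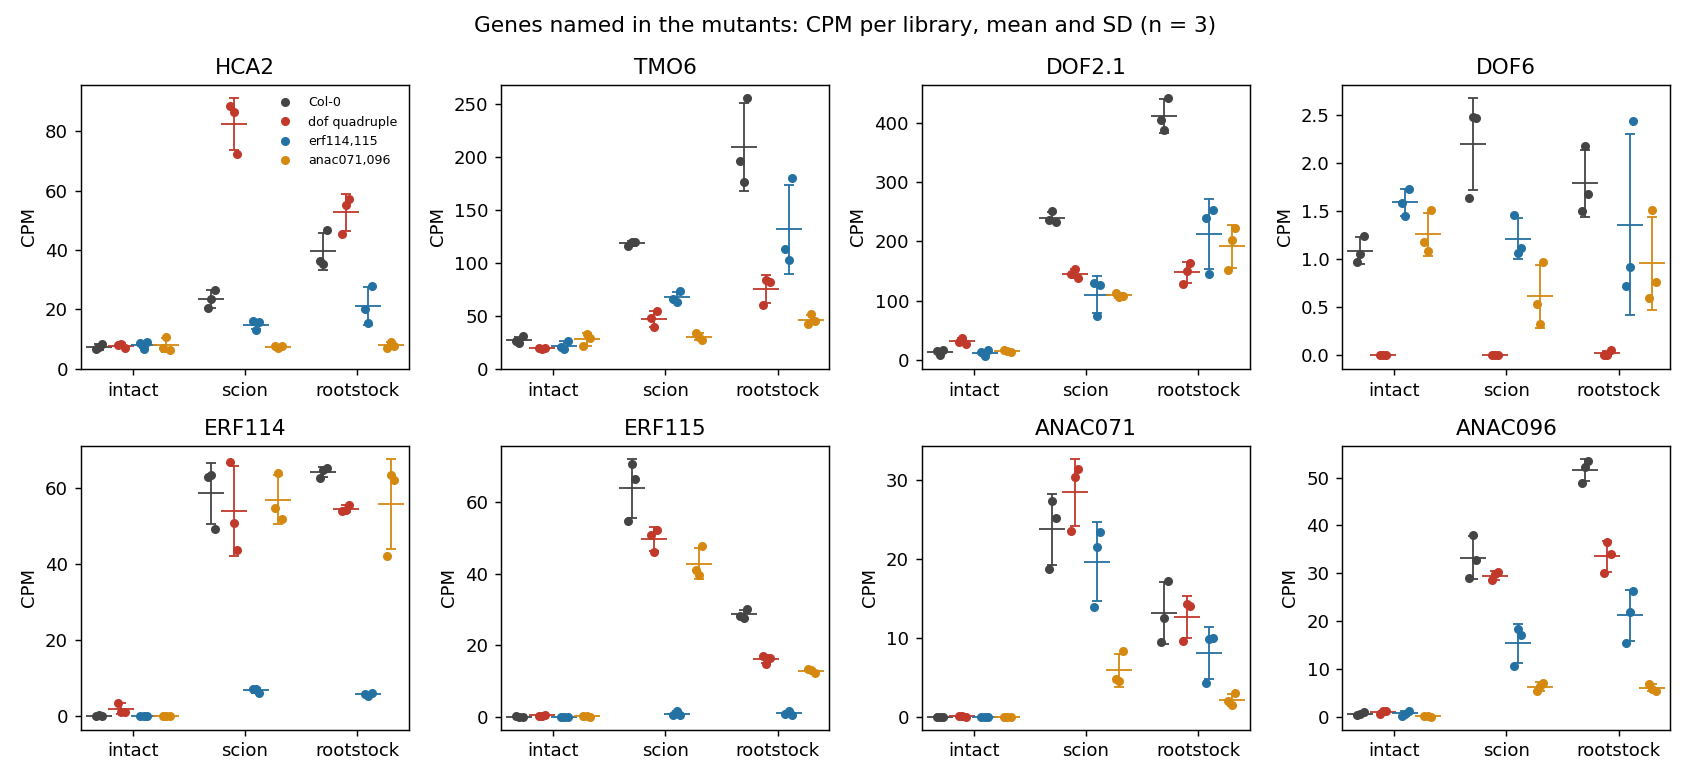
CPM of the 8 targeted genes in each of the 36 libraries, on linear axes, with points for libraries, lines for the group mean and bars for the SD of 3. DOF6 was at or near 0 in dof quadruple, ERF115 stayed below 1 CPM on average in erf114,115, and HCA2 in anac071,096 scions averaged 7.40 CPM against 23.6 in Col-0.

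The Col-0 scion was compared with the intact hypocotyl to find what the cut shoot side expressed after 24 h. Genes of cell division rose. PCNA1 rose from 1.31 ± 0.264 to 30.3 ± 0.930 CPM, by 4.53 ± 0.30 on the log2 scale (adjusted p 4.4e-13), and MCM7 from 1.83 ± 0.369 to 29.6 ± 3.28 CPM. Genes of photosynthesis fell, with PSAF going from 3014 ± 391.6 to 595 ± 101.4 CPM (log2 change -2.34 ± 0.16, adjusted p 9e-13). All targeted genes but DOF6 rose, ERF115 by 10.03 ± 0.50 (adjusted p 7.3e-15), or by a CPM ratio of 3230 without Col-0 intact replicate 1, which leaves 1 count. ERF114 rose by 8.34 ± 0.56. Without Col-0 intact replicate 2 that group had 0 counts of ERF114, and the scion was at least 856.8-fold higher. ANAC096 rose by 5.66 ± 0.36, DOF2.1 by 4.04 ± 0.28, TMO6 by 2.12 ± 0.20 and HCA2 by 1.66 ± 0.20 (adjusted p 3.2e-08). ANAC071 was at least 572.9-fold higher than the intact floor, and DOF6 changed by 1.01 ± 0.47 (adjusted p 0.0703), which did not pass. In all, 5655 genes rose and 4903 fell, or 10558 of 19476, and 6964 of them by at least 2-fold.

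The rises named by the fixed rule were in NDB4 (AT2G20800), at least 1456-fold higher at 60.5 ± 1.59 CPM, GSTU11, at least 349.2-fold, SDR2, at least 324.9-fold, ACS7, at least 254.3-fold, and the cellulase gene GH9B3 (AT1G71380). GH9B3 went from 0.0889 to 119.6 ± 20.3 CPM (log2 change 10.21 ± 0.42, adjusted p 2.9e-16), a CPM ratio of 2604 without Col-0 intact replicate 2, which leaves 2 counts. The falls were in CYP78A8, with 1 count against 1467 and a CPM ratio of 1648 (counting interval 295.3 to 65140), FBA5 (log2 change -9.14 ± 0.68, a CPM ratio of 2013 without Col-0 scion replicate 3, which leaves 2 counts), BT2, RL3 and GER3.

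All 12 genes of the DNA replication list rose, also when adjusted over the list alone, with a median of 3.36 (adjusted p 6.5e-11 and, with an estimated correlation, 0.00408). All 18 tested mitosis genes rose (18 adjusted over the list alone; median 3.26, adjusted p 5.5e-13 and 0.0324 with an estimated correlation). All 24 tested photosynthesis genes fell (24 adjusted over the list alone; median -2.50, adjusted p 6.5e-28 and 0.0271 with an estimated correlation).

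A further 4 lists passed with the preset correlation alone. Of 16 cambium genes 11 rose and 3 fell (11 and 3 adjusted over the list alone; median 1.21, adjusted p 0.00944), and adjusted p = 0.121 with an estimated correlation. LBD11 rose by 9.22 ± 0.63, WOX4 by 2.15 ± 0.19 and SMXL5 by 1.77 ± 0.14 (adjusted p 9.1e-12). Of 15 wound and regeneration regulators 8 rose and 1 fell (8 and 2 adjusted over the list alone; median 1.76, adjusted p 0.0257), and adjusted p = 0.185 with an estimated correlation. This call was lost without Col-0 intact replicate 3 (adjusted p 0.0678). LBD16 rose by 5.99 ± 0.50, to 23.3 ± 4.87 CPM, and PLT3 by 4.64 ± 0.44. Of 28 primary cell wall genes 13 rose and 4 fell (13 and 4 adjusted over the list alone; median 0.87, adjusted p 0.00483), and adjusted p = 0.413 with an estimated correlation. EXPA4 rose from 38.1 ± 2.95 to 1219 ± 82.8 CPM. Of 13 sugar starvation genes 1 rose and 7 fell (1 and 8 adjusted over the list alone; median -0.96, adjusted p 0.00632), and adjusted p = 0.576 with an estimated correlation. TPS8 fell by 2.79 on the log2 scale (SE 0.28).

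The other tested lists did not pass as lists. Of 20 phloem genes 8 rose and 6 fell (8 and 6 adjusted over the list alone; median -0.07 with the test leaning up, adjusted p 0.939). OPS rose from 16.8 ± 1.82 to 149 ± 15.4 CPM (log2 change 3.15 ± 0.15, adjusted p 1.1e-15) and SWEET11 fell from 62.5 ± 9.08 to 0.360 CPM (log2 change -7.43 ± 0.39). Of 24 other DOF family genes 5 rose and 9 fell (5 and 10 adjusted over the list alone; adjusted p 0.135). Of 19 xylem and secondary wall genes 1 rose and 5 fell (0 and 3 adjusted over the list alone; adjusted p 0.422). Of 23 jasmonate genes 8 rose and 7 fell (8 and 7 adjusted over the list alone; median -0.21, mean 0.23, adjusted p 0.918).

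Of 15 ethylene genes 3 rose and 7 fell (3 and 7 adjusted over the list alone; median -0.35, mean 1.29, adjusted p 0.687). Of 16 auxin response genes 7 rose and 4 fell (7 and 6 adjusted over the list alone; adjusted p 0.682). Of 11 cytokinin response genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; adjusted p 0.156). Of 7 sugar abundance genes 5 rose (5 adjusted over the list alone; adjusted p 0.294). Of 13 hypoxia genes 5 rose and 4 fell (6 and 5 adjusted over the list alone; median 0.30 with the test leaning down, adjusted p 0.937). Of 11 salicylate and defence genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p 0.718). Of 9 endodermis and suberin genes 3 rose (2 adjusted over the list alone; adjusted p 0.296). Of 7 epidermis and stomata genes 4 fell (4 adjusted over the list alone; adjusted p 0.199). Of 2 shoot meristem genes, CUC3 rose (1 adjusted over the list alone; adjusted p of the list 0.461). None of the 7 root hair genes had enough counts for the edgeR test, so this list was not tested.

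Below the junction, the Col-0 rootstock was compared with the same intact hypocotyls. Regulators of wounding rose, with RAP2.6L going from 9.10 ± 2.94 to 74.3 ± 8.78 CPM (log2 change 3.03 ± 0.24, adjusted p 2.4e-11). SEN1 of the sugar starvation list rose from 37.5 ± 19.5 to 1575 ± 358 CPM (5.39 ± 0.64, adjusted p 5.2e-08). XCP2 of the xylem list fell from 74.7 ± 20.9 to 8.82 ± 4.74 CPM (-3.09 ± 0.35, adjusted p 2e-08). Of the targeted genes, ERF115 rose by 8.87 ± 0.50 (a CPM ratio of 1436 without Col-0 intact replicate 1), ERF114 by 8.48 ± 0.57 (at least 933.4-fold higher without Col-0 intact replicate 2, which leaves 0 intact counts), ANAC096 by 6.29 ± 0.37, DOF2.1 by 4.82 ± 0.29, TMO6 by 2.94 ± 0.20 and HCA2 by 2.41 ± 0.20 (adjusted p 5.1e-11). ANAC071 was at least 310.1-fold higher, and DOF6 changed by 0.72 ± 0.47 (adjusted p 0.240). In all, 4410 genes rose and 3320 fell, 4924 of them by at least 2-fold. Of those called 57.05% rose, and upper-quartile scaling put that share at 47.9% and moved the median of all genes by -0.12. The rises named by the fixed rule included UPI, with a CPM ratio of 20100 (counting interval 3607 to 793800), DIN2 at 11.93 ± 1.24 (a CPM ratio of 5590 without Col-0 intact replicate 2, which leaves 3 counts), GSTU11, at least 963.3-fold higher, and ACS7, at least 673.2-fold. The falls included BCAT4 (AT3G19710), from 194.6 ± 9.13 to 0.0570 CPM (log2 change -11.47 ± 0.52), and CYP79F1, from 279 ± 43.1 to 0.154 CPM. Without Col-0 rootstock replicate 2, which leaves 1 and 2 counts, their CPM ratios were 7347 and 5373.

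Of 15 wound and regeneration regulators 9 rose (9 adjusted over the list alone; median 2.82, or 1.6 with genes at the bound, and 1.55 without Col-0 rootstock replicate 1). The list had adjusted p 3.3e-04 and, with an estimated correlation, 0.0271. All 18 mitosis genes rose (18 adjusted over the list alone; median 2.84, adjusted p 3.4e-15 and 0.0266 with an estimated correlation), as did 10 of 12 DNA replication genes (10 adjusted over the list alone; median 2.31, adjusted p 2.5e-07 and 0.0251). PCNA1 reached 14 ± 2.00 CPM. Of 19 xylem and secondary wall genes 15 fell (15 adjusted over the list alone; median -2.06, adjusted p 6.6e-06), and adjusted p = 0.121 with an estimated correlation. Of 13 sugar starvation genes 10 rose (10 adjusted over the list alone; median 1.59, adjusted p 2.3e-04), and adjusted p = 0.366 with an estimated correlation. Of 24 photosynthesis genes 14 fell (15 adjusted over the list alone; median -0.59, adjusted p 3.2e-04), and adjusted p = 0.576 with an estimated correlation. Of 7 sugar abundance genes 6 fell (6 adjusted over the list alone; median -4.46, adjusted p 0.0183), and adjusted p = 0.444 with an estimated correlation. Of 9 endodermis and suberin genes 4 rose (6 adjusted over the list alone; adjusted p 0.0419), and adjusted p = 0.576 with an estimated correlation.

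The cambium list also passed in the rootstock with the preset correlation, 8 genes rising and 2 falling of 16 (8 and 2 adjusted over the list alone; median 0.76, adjusted p 0.03996), and adjusted p = 0.192 with an estimated correlation. That call was lost without Col-0 intact replicate 2 (0.0574), intact replicate 3 (0.0537) or rootstock replicate 3 (0.0583), and with a replicate block (0.0559). LBD11 rose by 9.92 ± 0.64 and SMXL5 by 1.83 ± 0.14, and ER fell by 3.09 on the log2 scale (SE 0.21, adjusted p 9.4e-13). The epidermis and stomata list (adjusted p 0.0419, 0.357 with an estimated correlation) was lost without Col-0 intact replicate 2 (0.0606) or rootstock replicate 3 (0.0646), and with the block (0.0512). PDF1 fell by 5.90 (SE 0.78), and by a CPM ratio of 350.1 without rootstock replicate 1, which leaves 2 counts.

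The sides of the junction were compared directly within Col-0, to find genes that differ between the shoot side and the root side. Sugar starvation genes were lower in the scion. BGAL4 had 3.02 CPM in scions and 1508 ± 116.3 in rootstocks (log2 change -8.97 ± 0.87), and TPS8 had 29.3 ± 6.97 and 284 ± 21.2 CPM (-3.28 ± 0.29, adjusted p 1.8e-10). GH3.5 of the auxin response list was higher in the scion, at 220.6 ± 21.5 against 28.4 ± 6.20 CPM (2.96 ± 0.23, adjusted p 1.6e-11). Of the targeted genes, ERF115 was higher in the scion by 1.16 ± 0.28 (adjusted p 0.00145), and HCA2, TMO6 and DOF2.1 were lower, at -0.75 ± 0.19 (0.00196), -0.82 ± 0.19 (0.00069) and -0.78 ± 0.24 (0.00999). ANAC071 passed at 0.86 ± 0.32 (0.0323). Its call was lost without scion replicate 2 (0.106), scion replicate 3 (0.0784), rootstock replicate 1 (0.143) or rootstock replicate 2 (0.0837). ERF114 (-0.13 ± 0.36, adjusted p 0.786), ANAC096 (-0.63 ± 0.28, adjusted p 0.0603) and DOF6 (0.29, adjusted p 0.632) did not pass. In all, 4584 genes were higher and 4413 lower in the scion, 5104 of them by at least 2-fold. The share higher was 50.95%, and upper-quartile scaling put it at 59.35% and moved the median of all genes by 0.12. NAS1 was at least 274.2-fold higher there, and UPB1 at least 1268-fold lower.

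Of 13 sugar starvation genes 12 were lower in the scion (12 adjusted over the list alone; median -3.28, adjusted p 5.1e-13 and, with an estimated correlation, 0.0489). All 24 photosynthesis genes were lower (24 adjusted over the list alone; median -1.86, adjusted p 1.8e-23 and 0.0368), PSAF at 595 against 2511 ± 121 CPM. All 7 sugar abundance genes were higher (7 adjusted over the list alone; median 7.00, adjusted p 3.3e-04), and adjusted p = 0.192 with an estimated correlation. Of 19 xylem genes 12 were higher (12 adjusted over the list alone; median 1.58, adjusted p 7.6e-04), and adjusted p = 0.273 with an estimated correlation. Of 12 DNA replication genes 10 were higher (10 adjusted over the list alone; median 1.12, adjusted p 0.00332), and adjusted p = 0.186 with an estimated correlation, while 2 of 18 mitosis genes were higher and that list did not pass (adjusted p 0.525). Of 16 auxin response genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone; median 0.61, adjusted p 0.00853), and adjusted p = 0.444 with an estimated correlation. The auxin median was 0.39 without scion replicate 2, 0.28 without scion replicate 3 and 0.35 without rootstock replicate 2, with the call kept.

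**Figure D2:**
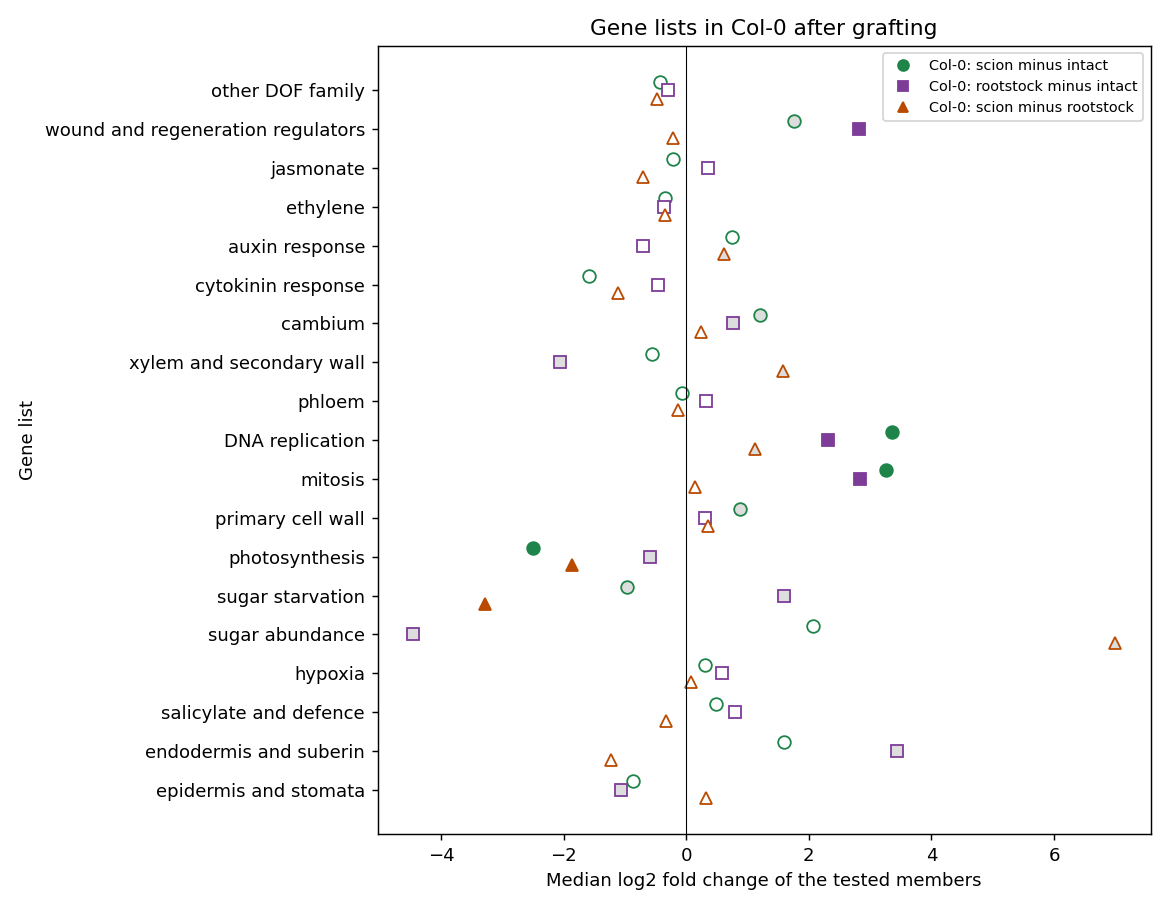
Median log2 change of each gene list in the 3 Col-0 comparisons, with circles for scion minus intact, squares for rootstock minus intact and triangles for scion minus rootstock. Filled marks passed with an estimated correlation, grey marks with the preset correlation alone and white marks with neither, and DNA replication and mitosis were filled on both sides of the junction.

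The same responses were measured within each mutant, against its own intact hypocotyls. In dof quadruple, HCA2 rose by 3.39 ± 0.21 in the scion (adjusted p 1.2e-13) and by 2.75 ± 0.20 in the rootstock, TMO6 by 1.28 ± 0.19 and 1.95 ± 0.20, and DOF2.1 by 2.17 ± 0.25 and 2.19 ± 0.25. ERF115 rose by 7.06 ± 0.40 and 5.43 ± 0.39, ERF114 by 4.81 ± 0.43 and 4.83 ± 0.44, and ANAC096 by 4.87 ± 0.34 and 5.05 ± 0.35. ANAC071 had CPM ratios of 744.9 (counting interval 254.6 to 3615) and 336.4 (114.7 to 1634). In the scion 5584 genes rose and 4980 fell, and in the rootstock 4451 rose and 3395 fell. There 56.7% rose, and upper-quartile scaling put that share at 50.2%, with a median shift of -0.08. All 12 DNA replication genes rose in the scion (12 adjusted over the list alone; median 3.34, adjusted p 4.7e-11 and 0.00665 with an estimated correlation), PCNA1 by 4.59 ± 0.30, and 11 in the rootstock (median 2.14, adjusted p 3.9e-08 and 0.0214). Mitosis genes rose, 18 of 18 in the scion (median 3.04, adjusted p 2.3e-13 and 0.0263) and 17 in the rootstock (median 2.87, adjusted p 3.6e-17 and 0.0185). All 24 photosynthesis genes fell in the scion (median -2.23, adjusted p 2.2e-25 and 0.0298). Of 15 wound and regeneration regulators 10 rose and 1 fell in the rootstock (median 1.98, or 1.8 at the bound, adjusted p 3.6e-04 and 0.0263), RAP2.6L by 3.68 ± 0.25. Xylem genes fell in the rootstock, 13 of 19 (15 adjusted over the list alone; adjusted p 2.1e-05), and adjusted p = 0.167 with an estimated correlation.

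In erf114,115, ERF115 was at least 22.4-fold higher in the scion than the intact floor and at least 24.9-fold in the rootstock, and ERF114 rose by 6.55 ± 0.64 (adjusted p 1.2e-09) and 6.30 ± 0.65. Without erf114,115 intact replicate 2 the intact group had 0 counts of ERF114, and scion and rootstock were at least 114.4-fold and at least 96.37-fold higher. HCA2 rose by 0.87 ± 0.19 in the scion (adjusted p 4.1e-04) and 1.38 ± 0.20 in the rootstock, TMO6 by 1.62 ± 0.19 and 2.59 ± 0.20, DOF2.1 by 3.11 ± 0.27 and 4.05 ± 0.28, and ANAC096 by 4.36 ± 0.35 and 4.82 ± 0.35. ANAC071 was at least 498.3-fold and at least 202.7-fold higher. In the scion 5586 genes rose and 4204 fell. In the rootstock 5235 rose and 3486 fell, so 60.0% rose, and 4702 passed in a fit of the compared groups only. Upper-quartile scaling put that share at 47.9% and moved the median of all genes by -0.17. All 12 DNA replication genes rose in the scion (12 adjusted over the list alone; median 3.33, adjusted p 1.8e-11 and 0.00665 with an estimated correlation), as did all 18 mitosis genes (median 3.55, adjusted p 5.4e-14 and 0.0264), and all 24 photosynthesis genes fell (median -2.3, adjusted p 3.6e-28 and 0.0263). In the rootstock 17 mitosis genes rose (18 adjusted over the list alone; median 3.43, adjusted p 1.5e-14 and 0.0263), and 17 of 19 xylem genes fell (median -2.88, adjusted p 1e-07), with adjusted p = 0.0741 with an estimated correlation.

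In anac071,096, HCA2 changed by -0.12 ± 0.20 in the scion (adjusted p 0.660) and by 0.00 ± 0.20 in the rootstock (0.998), and TMO6 by 0.12 ± 0.19 in the scion (0.630). TMO6 rose by 0.73 ± 0.19 in the rootstock (0.00259), and DOF2.1 rose by 2.76 ± 0.26 and 3.58 ± 0.27. ERF115 rose by 8.23 ± 0.46 and 6.51 ± 0.45, ANAC096 by 5.63 ± 0.46 and 5.58 ± 0.46 (CPM ratios of 96.03 and 91.89 without anac071,096 intact replicate 2, which leaves 3 counts), and ANAC071 was at least 129.4-fold and at least 46.96-fold higher. In the scion 5258 genes rose and 4468 fell. In the rootstock 4227 rose and 3198 fell, so 56.9% rose, and upper-quartile scaling put that share at 45.4%, with a median shift of -0.15. All 12 DNA replication genes rose in the scion (12 adjusted over the list alone; median 3.25, adjusted p 1.4e-11 and 0.00665 with an estimated correlation), and 10 in the rootstock (11 adjusted over the list alone; median 1.82, adjusted p 8e-06 and 0.0355). All 24 photosynthesis genes fell in the scion (median -2.41, adjusted p 7.1e-30 and 0.0263). Of 20 phloem genes 2 rose and 9 fell in the scion (adjusted p 0.107) and 3 rose and 8 fell in the rootstock (adjusted p 0.343). There BAM3 fell by 1.14 on the log2 scale (SE 0.16, adjusted p 9e-07), while OPS rose by 2.64 ± 0.15.

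Taken over the 10558 genes called in the Col-0 scion, 98% had the same sign in dof quadruple, 99.0% in erf114,115 and 98.9% in anac071,096. The slopes of mutant on Col-0 change were 0.78, 0.87 and 0.89. Over the 7730 genes called in the Col-0 rootstock the shares were 98%, 98.7% and 98.4% and the slopes 0.73, 0.99 and 0.91. In the scion 17, 4 and 8 of these genes passed with the opposite sign, and in the rootstock 7, 1 and 24. Choosing genes called in Col-0 can lower the slopes, so they are not compared with 1. Genes are not independent replicates.

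Each mutant was then compared with Col-0 in the same tissue. In intact dof quadruple hypocotyls, DOF6 was at least 28.3-fold lower (adjusted p 1.8e-06) and DOF2.1 was higher by 1.16 ± 0.25 (0.00308). HCA2 (0.08, adjusted p 0.940) and TMO6 (-0.48 ± 0.19, adjusted p 0.205) did not pass. ERF114 was higher by 3.41 ± 0.60 (2.8e-04), at 1.99 ± 1.41 against 0.152 CPM, and at least 25.87-fold higher without Col-0 intact replicate 2, which leaves 0 counts in Col-0. ERF115 passed at 2.61 (0.0271; a CPM ratio of 18.6 without Col-0 intact replicate 1, which leaves 1 count) and was lost without Col-0 intact replicate 2 (0.158) or 3 (0.106), or dof quadruple intact replicate 2 (0.0559) or 3 (0.122). The glucosinolate gene AOP3 (AT4G03050) had 255 ± 93.6 CPM against 0.0153, a ratio of 19520 (counting interval 3504 to 771200). The RNA gene AT7SL-1 (AT4G02970) had 0.115 against 43.5 ± 14.8 CPM (-8.50 ± 0.60), and RAP2.6 had 4.86 against 50.8 ± 8.75 CPM (-3.37 ± 0.42, adjusted p 1.5e-06). In all, 557 genes were higher and 336 lower, and 595 passed in a fit of the compared groups only. Of 9 endodermis and suberin genes 6 were higher (8 adjusted over the list alone; median 4.22, adjusted p 1.5e-06), and adjusted p = 0.223 with an estimated correlation. ASFT had 22.9 ± 13.4 against 1.25 CPM, and the summed CASP1 to CASP5 level was 117 against 2.61 CPM, or 75.8 in the mutant without its replicate 1 and 0.45 in Col-0 without its replicate 3. Of 7 sugar abundance genes 3 were lower (adjusted p 0.00156, and 0.431 with an estimated correlation).

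In the dof quadruple scion, DOF6 was at least 59.1-fold lower (adjusted p 1.8e-07), TMO6 was lower by -1.33 ± 0.19 (2.7e-05), and HCA2 was higher by 1.81 ± 0.19 (1.5e-07). DOF2.1 (-0.72 ± 0.24, adjusted p 0.235) did not pass. GH9B3, named among the rises of the Col-0 scion, was lower at 45.8 ± 7.88 against 119.6 ± 20.3 CPM (-1.39 ± 0.25, adjusted p 8.7e-04). BCAT4 had 0.221 against 11.4 ± 2.90 CPM (-5.64 ± 0.42, adjusted p 2.4e-10), and BAT5 was at -6.35 ± 0.64. CYP71B19 was higher at 39.6 ± 1.8 against 3.87 ± 0.904 CPM (3.35 ± 0.39, adjusted p 6.7e-07). In all, 77 genes were higher and 215 lower. With loci of chromosome 4 not counted, an alternative chosen after seeing the data, the total was 181, and in a fit of the compared groups only 605. Of 7 sugar abundance genes 4 were lower (median -3.02, adjusted p 1.2e-05), and adjusted p = 0.223 with an estimated correlation. The jasmonate and other DOF family lists passed with small medians of 0.20 (0.0241) and 0.12 (0.0223), and neither held with an estimated correlation (0.434 and 0.605). Both calls were lost without dof quadruple scion replicate 3 (0.0717 and 0.0786), the jasmonate call also without Col-0 scion replicate 3 (0.122) and the DOF call without replicate 1 (0.0713).

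In the dof quadruple rootstock, TMO6 was lower by -1.47 ± 0.19 (adjusted p 4.8e-06), DOF2.1 by -1.48 ± 0.25 (2.3e-04) and DOF6 by a CPM ratio of 123.5 (counting interval 21.7 to 4920). HCA2 (0.42 ± 0.19, adjusted p 0.291) and ERF115 (-0.84, adjusted p 0.112) did not pass. GH9B3 had 42.6 ± 4.7 against 139 ± 11 CPM (-1.71 ± 0.25, adjusted p 4.1e-05), and RAP2.6 6.11 against 49.5 CPM (-3.03 ± 0.41). The resistance gene SNC1 (AT4G16890) had 10.9 ± 4.30 against 119 ± 20.3 CPM (-3.44 ± 0.39, adjusted p 5.5e-07). CYP705A1 (AT4G15330) was higher at 17.0 ± 1.04 against 0.466 CPM (5.18 ± 0.45, adjusted p 2.4e-09), and CRK41 at 4.54 ± 0.52. BAM3 was lower by -0.69 ± 0.16 (0.00862) and was lost without Col-0 rootstock replicate 3 (0.0763) or dof quadruple rootstock replicate 1 (0.0522). In all, 320 genes were higher and 407 lower. The total was 376 without dof quadruple rootstock replicate 2. The summed CASP1 to CASP5 level was 457 against 18.3 CPM. Of 13 sugar starvation genes 1 was lower (2 adjusted over the list alone; median -0.60, or -0.38 without dof quadruple rootstock replicate 2; adjusted p 0.00101), and adjusted p = 0.606 with an estimated correlation. The photosynthesis list passed with a median of -0.24 (0.0233), and adjusted p = 0.838 with an estimated correlation. It was lost without Col-0 rootstock replicate 1 (0.0985) or 3 (0.0552) or dof quadruple rootstock replicate 2 (0.195).

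Loci called with the same sign in all 3 tissues of dof quadruple gathered on chromosome 4. There were 150 of them, 36 higher and 114 lower, 145 of them nuclear. Chromosome 4 held 71, or 49.0%, against 14.9% of the other tested nuclear genes, and all 71 lay between 100919 and 10529092 in TAIR10.1. AOP3, AT7SL-1, SNC1, BAT5, MSRB4, CYP705A1 and CRK41 were among them, and ANAC071 lies in this stretch. A stretch of 300 tested genes on chromosome 1 (11685235 to 17376091) and another on chromosome 2 (3251566 to 7934353) held 16 calls each.

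**Figure D3:**
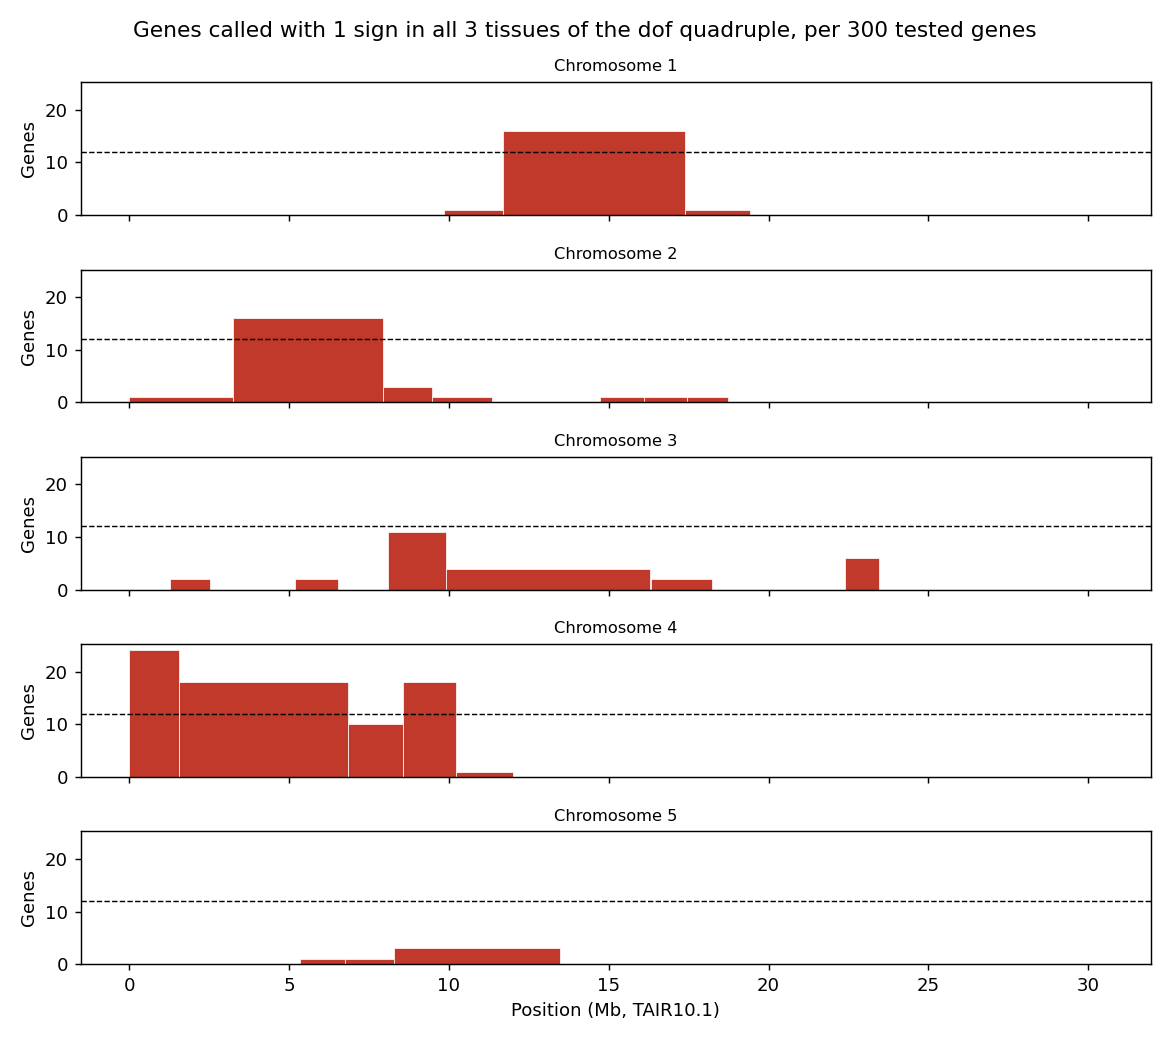
Calls of 1 sign in all 3 tissues of dof quadruple against Col-0 per stretch of 300 tested genes, end to end along the 5 chromosomes (dashed line at 12, the highest of random draws). The peak, 24, is on chromosome 4.

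**Figure D4:**
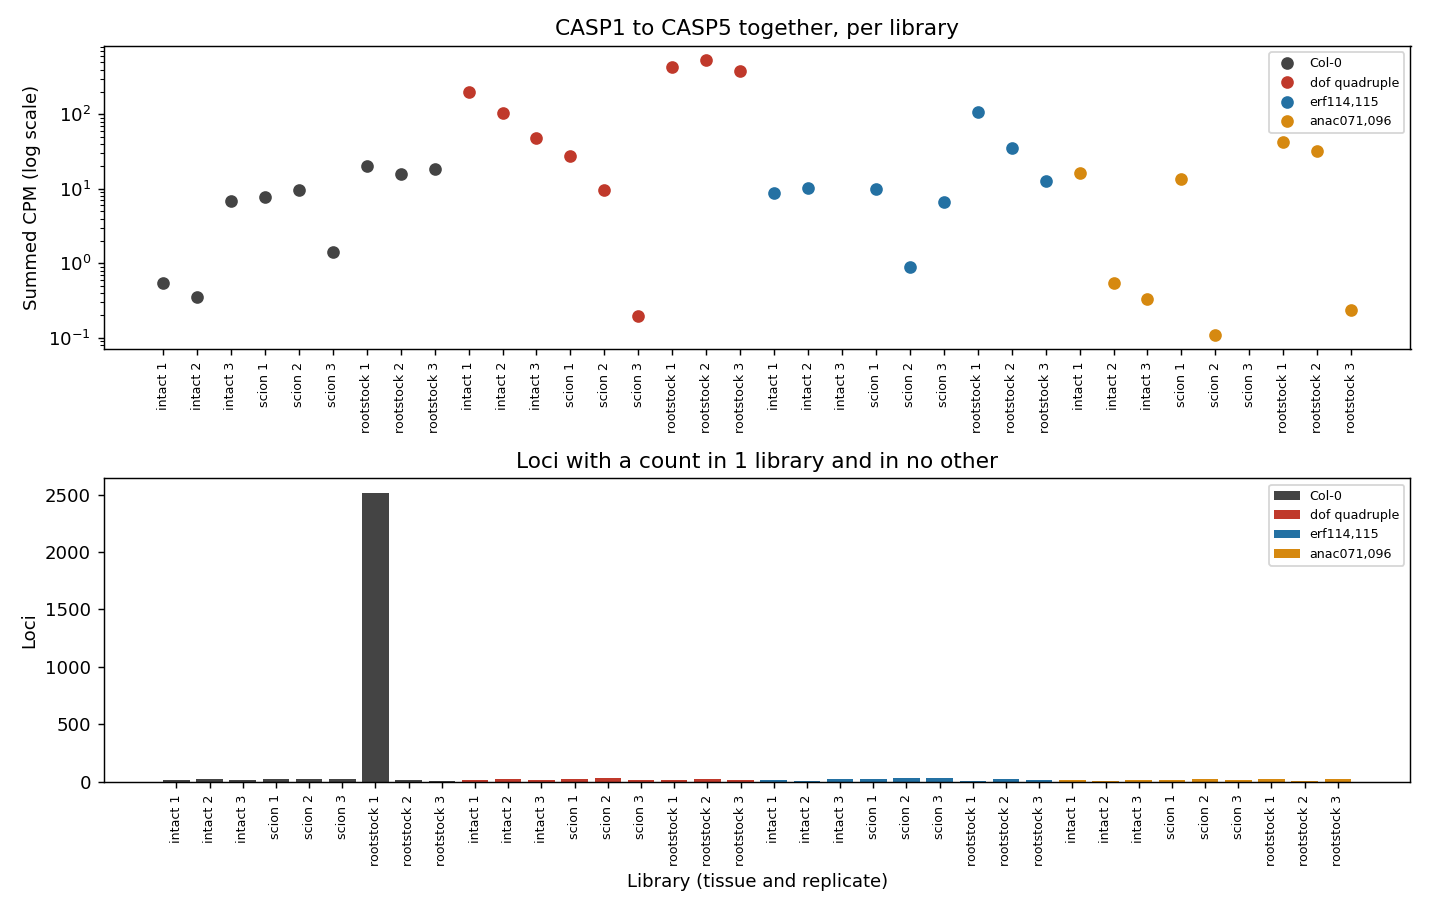
Top, summed CPM of CASP1 to CASP5 in each library on a log scale, with the libraries at 0 (erf114,115 intact replicate 3 and anac071,096 scion replicate 3) not drawn. Bottom, the number of loci counted in that library alone, which was 2514 in Col-0 rootstock replicate 1 and at most 34 elsewhere.

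In intact erf114,115 hypocotyls, 3 genes were higher and 3 lower than in Col-0 by edgeR, with 645 at an unadjusted p under 0.05 and 10 passing by DESeq2. The total was 1 in a fit of the compared groups only and 3 without erf114,115 intact replicate 2. None of the targeted genes passed. ERF115 had 0 counts against 4, which is near the floor, and ERF114 5 against 13 counts (-1.30 ± 1.04, adjusted p 0.969). Mitosis genes were lower as a list (median -0.80, adjusted p 1.1e-09), and adjusted p = 0.158 with an estimated correlation. No mitosis gene passed by edgeR over all genes and 5 did adjusted over the list alone, and CDKB2;1, the most abundant, was at -0.70 ± 0.32 (adjusted p 0.969).

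In the erf114,115 scion, ERF115 was lower by -6.15 ± 0.37 (adjusted p 4.9e-12) and ERF114 by -3.09 ± 0.39 (1.1e-05). HCA2 (-0.66 ± 0.19, adjusted p 0.109) and ANAC071 (-0.27 ± 0.32, adjusted p 0.812) did not pass. TMO6 passed at -0.81 ± 0.19 (0.0250) and was lost without each of the 6 libraries (0.0557 to 0.121). DOF2.1 passed at -1.11 ± 0.25 (0.0151) and was lost without Col-0 scion replicate 1 (0.0533) or 2 (0.0666) or erf114,115 scion replicate 2 (0.162). ANAC096 passed at -1.11 ± 0.28 (0.0476) and was lost without each of the 6 (0.0778 to 0.232). GH9B3 was lower at 25.2 ± 4.65 against 119.6 ± 20.3 CPM (-2.25 ± 0.25, adjusted p 3e-06). OPS was at 77.6 ± 12.5 against 149 ± 15.4 CPM (-0.94 ± 0.14, adjusted p 0.00015). In all, 69 genes were higher and 105 lower. The total of 174 was 301 with a replicate block, 353 by limma-voom and 379 by DESeq2. It was 94 and 109 without Col-0 scion replicates 1 and 2 and 107 without erf114,115 scion replicate 2.

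No list held in the erf114,115 scion with an estimated correlation. Primary cell wall genes had a median of -0.17 (adjusted p 1.8e-04), 2 of 28 being lower (3 adjusted over the list alone), and adjusted p = 0.372 with an estimated correlation. Mitosis genes had a median of -0.57 (3.4e-06), with 0 passing by edgeR in either adjustment, and adjusted p = 0.339 with an estimated correlation. The xylem and secondary wall list had a median of -0.46 (0.00376), and adjusted p = 0.587 with an estimated correlation. The xylem call was lost without Col-0 scion replicate 3 (0.0852) or erf114,115 scion replicate 1 (0.208).

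In the erf114,115 rootstock, ERF115 was lower by -4.83 ± 0.36 (adjusted p 2.1e-09) and ERF114 by -3.48 ± 0.40 (3.3e-06). TMO6 (-0.67 ± 0.19, adjusted p 0.149) and DOF2.1 (-0.95 ± 0.24, adjusted p 0.0885) did not pass. HCA2 passed at -0.90 ± 0.19 (0.0214) and was lost without Col-0 rootstock replicate 3 (0.116) or erf114,115 rootstock replicate 1 (0.114) or 2 (0.189). ANAC096 passed at -1.28 ± 0.28 (0.0273). It was lost without Col-0 rootstock replicate 1 (0.0641), 2 (0.0602) or 3 (0.0701) or erf114,115 rootstock replicate 1 (0.206) or 2 (0.0919). TH8 was at 3.57 ± 2.33 against 41.6 ± 13.5 CPM (-3.56 ± 0.41), XTH20 at -3.21 ± 0.55, EXPA8 at -3.13 ± 0.55 and BAM3 at 59.8 ± 15.5 against 114.8 ± 15.8 CPM (-0.94 ± 0.16, adjusted p 0.00146). A fit of these 6 libraries alone ended the calls of HCA2, ANAC096, TH8, XTH20, EXPA8 and BAM3. In all, 9 genes were higher and 65 lower. The total of 74 was 4 in that fit and 188 by DESeq2, 47 without erf114,115 rootstock replicate 1 and 111 without replicate 3.

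DNA replication genes were lower in the erf114,115 rootstock as a list (median -0.55, adjusted p 5.1e-07 and 0.0346 with an estimated correlation), with 0 of 12 passing by edgeR over all genes and 3 adjusted over the list alone. Cambium genes were lower as well (median -0.36, adjusted p 3.9e-05 and 0.0243), 1 of 16 over all genes and 4 adjusted over the list alone. That gene, SMXL5, was at 97.2 ± 6.05 against 155.6 ± 11.9 CPM (-0.68 ± 0.13, adjusted p 0.0109). It was lost without Col-0 rootstock replicate 3 (0.0604) or erf114,115 rootstock replicate 1 (0.0617) or 3 (0.0501). Primary cell wall genes, 4 of 28 lower (6 adjusted over the list alone; adjusted p 1.1e-04), had adjusted p = 0.339 with an estimated correlation. Their median was -0.06, and from -0.23 to 0.04 with single libraries left out.

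In intact anac071,096 hypocotyls, 5 genes were higher and 3 lower than in Col-0 by edgeR, with 505 at an unadjusted p under 0.05, 15 passing by DESeq2 and 3 in a fit of the compared groups only. LACS2 (AT1G49430) was higher at 120.2 ± 24.7 against 21.5 ± 4.57 CPM (2.48 ± 0.26, adjusted p 1.4e-06), and APS4 (AT5G43780) lower at 1.02 ± 0.790 against 28.4 ± 9.47 CPM (-4.71 ± 0.41, adjusted p 5.3e-08). ANAC096 was at -2.36 ± 0.56 (adjusted p 0.259), and no targeted gene passed.

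In the anac071,096 scion, ANAC071 was lower by -2.01 ± 0.33 (adjusted p 0.00257) and ANAC096 by -2.39 ± 0.29 (1.4e-05). HCA2 and TMO6 were lower too, at 7.40 ± 0.382 against 23.6 ± 3.11 CPM (-1.67 ± 0.20, adjusted p 1e-05) and 30.5 ± 3.16 against 118.6 ± 2.24 CPM (-1.96 ± 0.20, adjusted p 9.6e-07). DOF2.1 passed at -1.13 ± 0.25 (0.0221) and was lost without each of the 6 libraries (0.0721 to 0.161). ERF114 (-0.04 ± 0.36, adjusted p 1.0) and ERF115 (-0.58 ± 0.28, adjusted p 1.0) did not pass. Phloem genes were lower: 5 of 20 over all genes, and 12 lower and 1 higher adjusted over the list alone (median -0.68, adjusted p 1.2e-17 and 1.8e-04 with an estimated correlation). CALS7 had 2.18 ± 1.01 against 12.2 ± 0.587 CPM (-2.48 ± 0.36) and BAM3 60.5 ± 4.46 against 127.4 ± 8.34 CPM (-1.07 ± 0.16, adjusted p 0.0002). Cambium genes were lower as a list (median -0.24, or -0.15 without Col-0 scion replicate 2; adjusted p 8.1e-05 and 0.0268 with an estimated correlation), SMXL5 by -1.0 ± 0.14, as 1 of 16 (2 adjusted over the list alone). Mitosis genes had a median of -0.36 (1.2e-05), and adjusted p = 0.339 with an estimated correlation. The photosynthesis median of 0.18 passed (0.00131), and adjusted p = 0.730 with an estimated correlation. That call was lost without Col-0 scion replicate 2 (0.284) or anac071,096 scion replicate 1 (0.794). In all, 5 genes were higher and 70 lower. The total of 75 was 179 in a fit of the compared groups only, 120 by limma-voom and 155 by DESeq2, and 36, 42 and 33 without anac071,096 scion replicates 1, 2 and 3.

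In the anac071,096 rootstock, ANAC071 was lower by -2.60 ± 0.36 (adjusted p 0.0001) and ANAC096 by -3.08 ± 0.30 (1e-07). HCA2 had 8.03 ± 0.933 against 39.5 ± 6.36 CPM (-2.3 ± 0.20, adjusted p 1.5e-08) and TMO6 46.7 ± 4.58 against 209.9 ± 41.5 CPM (-2.17 ± 0.20, adjusted p 2.4e-08). DOF2.1 passed at -1.10 ± 0.25 (0.0176) and was lost without Col-0 rootstock replicate 3 (0.0680) or anac071,096 rootstock replicate 1 (0.202) or 2 (0.0614). ERF115 was at -1.15 ± 0.29 (0.0516) and ERF114 at -0.20 ± 0.36 (1.0). Of 20 phloem genes 8 were lower (9 adjusted over the list alone; median -0.82, adjusted p 9.7e-24 and 2.6e-05 with an estimated correlation). BAM3 had 36.3 ± 7.09 against 114.8 ± 15.8 CPM (-1.66 ± 0.16, adjusted p 9.4e-08), SEOR1 14.1 ± 3.46 against 51.6 ± 6.94 CPM (-1.87 ± 0.30), and NAC45 and CALS7 were at -3.05 ± 0.55 and -2.52 ± 0.39. Cambium genes were lower (median -0.35, adjusted p 1.3e-09 and 4.7e-04), 2 of 16 and 3 adjusted over the list alone, with SMXL5 at -1.62 ± 0.14 (1.1e-08). APS4 (-5.48 ± 0.42) and SUS6 (-4.11 ± 0.54) were among the lower genes. LACS2 was higher by 1.49 ± 0.25 (0.00071). In all, 13 genes were higher and 155 lower. The total was 65 in a fit of the compared groups only and 84 without anac071,096 rootstock replicate 1.

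**Figure D5:**
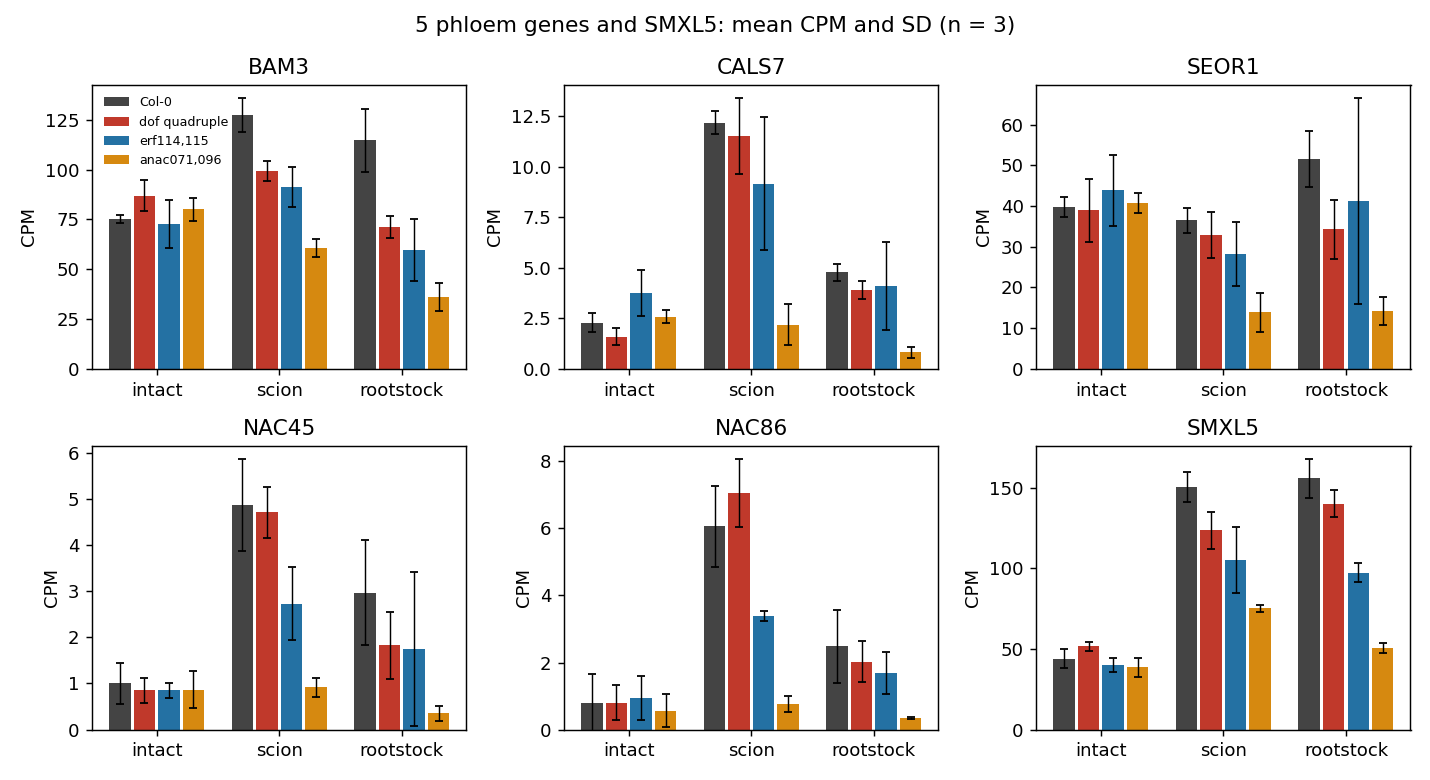
Mean CPM and SD of 3 libraries for BAM3, CALS7, SEOR1, NAC45, NAC86 and SMXL5 in the 12 groups, on linear axes from 0. BAM3 averaged 36.3 CPM in anac071,096 rootstocks and 114.8 in Col-0 rootstocks.

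The changes of the 3 mutants against Col-0 were correlated across genes, with the same Col-0 libraries in each. In rootstocks r was 0.27 for dof quadruple with erf114,115, 0.34 for dof quadruple with anac071,096 and 0.59 for erf114,115 with anac071,096. Simulated groups without any effect against shared simulated controls gave means of 0.49 to 0.51. The covariances were 0.188, 0.235 and 0.315, against simulated values of 0.131, 0.130 and 0.130, so the differences were 0.0574, 0.105 and 0.185. In scions r was 0.17, 0.24 and 0.51, and the covariances differed from the simulated ones by -0.0406, -0.0205 and 0.0538. In intact tissue r was 0.29, 0.32 and 0.39, with differences of 0.0467, 0.067 and 0.00832. In rootstocks dof quadruple and anac071,096 shared 8 higher and 23 lower calls (0.214 and 3.24 from independent lists) with 0 opposite, erf114,115 and anac071,096 4 and 11 (0.00601 and 0.517) with 0, and dof quadruple and erf114,115 6 and 9 (0.148 and 1.36) with 2. In scions, in the same order, they were 1 and 2 (0.0198 and 0.773) with 1, 2 and 10 (0.0177 and 0.377) with 0, and 9 and 4 (0.273 and 1.16) with 4. In intact tissue each pair shared 1 or 2 higher and 1 lower. The simulated groups shared at most 1 call for erf114,115 and anac071,096 scions and 0 for every other pair (10 draws). With 3 Col-0 libraries per tissue the controls could not be split, so part of these excesses may come from the shared controls.

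The grafting response of each mutant was last compared with that of Col-0, which is a test of the difference itself. In the dof quadruple scion, HCA2 responded more than in Col-0, by 1.73 ± 0.27 (adjusted p 3.6e-04), and DOF2.1 less, by -1.87 ± 0.35 (0.00265). ERF114 differed by -3.53 ± 0.71 (0.00607), where the intact level of the mutant was the higher. Without Col-0 intact replicate 2 that group had 0 counts of ERF114, so no difference is given. TMO6 (-0.85 ± 0.27, adjusted p 0.194) and ERF115 (-2.97 ± 0.77, adjusted p 0.0593) did not pass. CSD2 responded more, by 1.86 ± 0.33 (0.0016), and IOS1 less, by -5.33 ± 0.70 (2.6e-05). In all, 13 genes differed upward and 171 downward. The total of 184 was 306 by DESeq2, 114 without Col-0 intact replicate 3, 116 without Col-0 scion replicate 2 and 114 without dof quadruple intact replicate 1. Of 9 endodermis and suberin genes 3 differed downward (6 adjusted over the list alone; median -4.08, adjusted p 1.6e-09), and adjusted p = 0.0789 with an estimated correlation.

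In the dof quadruple rootstock, DOF2.1 responded less by -2.63 ± 0.35 (adjusted p 2.6e-05). ERF114 differed by -3.65 ± 0.71 (0.00468), from a higher intact level in the mutant. Without Col-0 intact replicate 2 (0 counts left) no value is given. ERF115 passed at -3.45 ± 0.76 (0.0178) and was lost without Col-0 intact replicate 2 (0.105) or 3 (0.0757) or dof quadruple intact replicate 3 (0.0795). Col-0 intact holds 4 counts of it, and 1 without replicate 1. HCA2 (0.34 ± 0.27, adjusted p 0.962) and TMO6 (-0.99 ± 0.27, adjusted p 0.0747) did not pass. GASA6 responded more, by 3.3 ± 0.69 (0.0102), and WRKY53 less, by -5.41 ± 0.72 (2.6e-05; no value is given without Col-0 intact replicate 1, which leaves 3 counts). In all, 32 genes differed upward and 143 downward, and the total was 102 by limma-voom, 296 by DESeq2 and 114 without Col-0 intact replicate 3. Of 9 endodermis and suberin genes 1 differed, FAR1 by -3.05 ± 0.63 (0.00866; no value is given without Col-0 intact replicate 2, which leaves 2 counts in that group), and that list (median -1.62, adjusted p 0.00139) had adjusted p = 0.536 with an estimated correlation.

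The erf114,115 responses differed from those of Col-0 in 4 genes upward and 6 downward in the scion, and in 3 upward and 6 downward in the rootstock, none of them targeted. In the scion SWEET11 responded more, by 2.97 ± 0.47 (adjusted p 0.0033), and DOT1 and UGT76C2 less, by -1.54 ± 0.24 (0.0033) and -1.40 ± 0.25 (0.00922). In the rootstock FLA15, with 4 counts in erf114,115 rootstocks, responded less by -4.37 ± 0.69 (0.00331), a call lost without erf114,115 rootstock replicate 2 (0.0608). The scion total was 25 with a replicate block, 2 in a fit of the compared groups only, 5 by limma-voom, 65 by DESeq2 and 17 without erf114,115 intact replicate 1. The rootstock total was 3 in that fit, 2 by limma-voom, 35 by DESeq2, 4 without erf114,115 intact replicate 3 or rootstock replicate 2, and 18 without rootstock replicate 3. The xylem and secondary wall list differed, with medians of -0.61 in the scion (2.6e-05) and -0.89 in the rootstock (0.00187), and adjusted p = 0.346 and 0.555 with an estimated correlation. The scion median was -0.26 without Col-0 scion replicate 3, and the rootstock call was lost without Col-0 rootstock replicate 3 (0.0888).

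In the anac071,096 scion, HCA2 and TMO6 responded less than in Col-0, by -1.78 ± 0.28 (adjusted p 0.00327) and -2.00 ± 0.27 (6.6e-04), and 1 gene differed upward and 8 downward. The total was 3 by limma-voom, 44 by DESeq2, 3 without Col-0 intact replicate 2 and 6 without anac071,096 intact replicate 2, and 4 or 5 without each of the other 10 libraries compared. Phloem genes responded less (median -0.71, or -0.46 without anac071,096 intact replicate 2; adjusted p 5e-09 and 0.0115 with an estimated correlation), 2 of 20 over all genes, and 9 less and 1 more adjusted over the list alone. In the rootstock, HCA2 and TMO6 responded less by -2.41 ± 0.28 and -2.21 ± 0.27 (3e-05 for both), BAM3 by -1.75 ± 0.22 (4.5e-05), SMXL5 by -1.43 ± 0.19 (8.7e-05) and SUS6 by -3.83 ± 0.70 (0.0099). There 1 gene differed upward and 39 downward, and the total of 40 was 10 in a fit of the compared groups only, 15 by limma-voom, 103 by DESeq2, 21 and 19 without Col-0 intact replicates 2 and 3, and 23 without Col-0 rootstock replicate 3. It was 21 without anac071,096 intact replicate 2, and 18 and 20 without anac071,096 rootstock replicates 1 and 3. Of 20 phloem genes 3 responded less (6 adjusted over the list alone; median -0.61, or -0.96 without Col-0 intact replicate 2; adjusted p 1.8e-15 and 5.7e-04 with an estimated correlation). Cambium genes differed by a median of -0.23 (7.3e-04), and adjusted p = 0.0690 with an estimated correlation. That median was -0.08 without Col-0 rootstock replicate 3.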

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

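The counts of dof quadruple calls along and per chromosome, both tests on Col-0 rootstock replicate 1 and the root hair test were chosen after the results they concern were seen. The splits of the libraries, the test of calls near the targeted genes and the test of root meristem genes were written before.

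Calls of 1 sign in all 3 tissues of dof quadruple lay together along the chromosomes. A first count, of calls with another such call 11 to 300 tested loci away, gave 134 of 145 against a random mean of 142.4 and a random highest of 145, a measure near its ceiling that decides nothing, and it was replaced. The most calls in any 300 consecutive tested genes were 29, against a mean of 7.49 and a highest of 12 in 1000 random draws, and 49.0% of the calls lay on chromosome 4 against 14.9% of the other tested genes (odds ratio 5.47, Fisher's exact p 8.4e-22), which argues against loss of the 4 DOF genes acting across the genome as the source of the whole pattern. Only 1 of 144 calls lay within 300 loci of a targeted gene, an odds ratio of 0.101 (two-sided Fisher's exact p 0.00164, interval 0.00255 to 0.574), which argues against sequence linked to those genes, while the same ratio was 0 for erf114,115 and 0 for anac071,096, on 4 calls each, too few to decide. The gathering was not confined to chromosome 4, since a stretch of 300 tested genes on chromosome 1 and another on chromosome 2 held 16 calls each, also above 12. Strain variants in these stretches of the dof quadruple line are a candidate explanation, and effects of the genotype itself stay open for the other calls.

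Col-0 rootstock replicate 1 stood out by signal where other libraries had none, with 2514 loci counted in it alone and at most 34 in any other library. Of 4549 protein-coding loci at 0 in the other 35 libraries it counted 2102, from 20.3% of the shortest to 69.0% of the longest of 4 equal classes by length (Spearman rho 0.38 across loci, which are not independent replicates). The 12 seed storage genes, all abundant seed transcripts, held 387 CPM in it and at most 9.34 elsewhere, a ratio of 41.5. PAP85 (106 CPM), SESA5 (72.4) and OLEO1 (70.9) carried much of the sum, while SESA2 was at 0, SESA1 at 0.2 and CRU2 at 2.75 CPM. Genomic DNA and RNA from seeds are both candidate explanations, and neither test argues against the other. The low members speak against a uniform rise of seed transcripts, and with no seed library to compare they do not exclude RNA from seeds. No biological explanation was tested, since replicates of a group share their treatment in the labels.

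CASP1 to CASP5, genes of the root endodermis, summed to 117 ± 76.3 CPM in dof quadruple against 2.61 ± 3.74 in Col-0 in intact tissue and 457 ± 79.2 against 18.3 ± 2.46 in rootstocks (SD of 3). From replicate 1 to 3 dof quadruple had 199, 103 and 48.3 in intact tissue and 439, 543 and 387 in rootstocks. Rootstocks of erf114,115 held 12.8 to 107 and of anac071,096 0.238 to 43.25. In scions the libraries overlapped, at 0.194 to 27.2 against 1.42 to 9.66. The 7 root hair genes rose by no more than 0.00899% of the CASP rise, which argues against root tissue with root hairs in the pieces. Of 9 root meristem and lateral root primordium genes 0 were higher by edgeR, but 3 were tested, so root meristems or primordia in the pieces cannot be told apart from their absence. More endodermis in the pieces and a genotype effect on these genes may both remain, the latter untested.

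The next results stood out because a mutant's grafting response differed from that of Col-0 in a test of the difference. In dof quadruple 184 genes differed in the scion and 175 in the rootstock, in erf114,115 10 and 9, and in anac071,096 9 and 40. In dof quadruple scions HCA2 differed by 1.73, DOF2.1 by -1.87 and ERF114 by -3.53. In dof quadruple rootstocks DOF2.1 differed by -2.63, ERF114 by -3.65 and ERF115 by -3.45. Without Col-0 intact replicate 2 that group had 0 counts of ERF114. In anac071,096 HCA2 differed by -1.78 in the scion and -2.41 in the rootstock, and TMO6 by -2.00 and -2.21.

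Lists differed by these medians. In dof quadruple scions they were -0.36 for cambium, 0.20 for photosynthesis and -4.08 for endodermis and suberin, and in its rootstocks -0.36 for cambium, -0.56 for sugar starvation and -1.62 for endodermis and suberin. In erf114,115 scions they were 0.34 for ethylene and -0.61 for xylem, and in its rootstocks -0.27 for cambium, -0.89 for xylem, -0.39 for phloem and 0.53 for sugar starvation. In anac071,096 scions they were -0.71 for phloem and -0.40 for mitosis, and in its rootstocks -0.23 for cambium, 0.61 for xylem and -0.61 for phloem. With an estimated correlation the phloem medians of anac071,096 still passed (0.0115 and 5.7e-04), and the others did not.

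Other splits of the 12 libraries of each response difference were fitted on those libraries alone, 33 each, without a replicate block. A split that exchanges the genotypes in 1 tissue alone turns a genotype difference shared by the tissues into a difference in response. It was among the splits of 4 tests, and leaving it out was chosen after the counts were seen. By these splits chance could not be excluded, with or without that split, for dof quadruple scions, both erf114,115 counts and anac071,096 rootstocks. For dof quadruple rootstocks and anac071,096 scions the exchange was the only other split as large, and without it 1 of 32 splits, the real one, called as many genes, so whether chance is excluded rests on that choice. For dof quadruple scions the real split called 187 genes, the highest other 1110, and 5 splits called as many as the real one. For dof quadruple rootstocks these numbers were 137, 1498 and 2. For erf114,115 they were 2, 29 and 6 in scions and 3, 8 and 4 in rootstocks. For anac071,096 they were 12, 41 and 2 in scions and 10, 35 and 6 in rootstocks. The exchange gave the highest count in both dof quadruple tests, erf114,115 rootstocks and anac071,096 scions, and the highest of the remaining splits called 259, 97, 3 and 11 genes. The highest splits of erf114,115 scions and anac071,096 rootstocks parted intact replicates 1 of both genotypes from intact replicates 3 of both. They also kept the graft tissue parted by genotype. Either may make a split call more genes than chance alone would, so for these 2 counts the question stays open. With a block the real splits called 25 and 45 genes in the fit of all groups, and the other splits were not fitted.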

How the results depend on the processing

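Every count of called genes stayed within 1.5 times its value with RLE size factors, upper-quartile scaling and no low-count filter. Of 1001 passing results of single named genes, 998 passed with RLE, 999 with upper-quartile scaling, 973 without the filter, 991 by DESeq2, 949 by limma-voom and 908 with the compared groups only, all in the same direction. Of 124 passing lists, all but 1 passed with RLE and 113 without the filter, in the same direction. By fry 81 passed, and 30 with an estimated correlation. Genes that passed only under the alternative numbered 4 with RLE, 10 with upper-quartile scaling, 1 without the filter, 34 by DESeq2, 29 by limma-voom and 28 with the compared groups only, and such lists 1 with RLE, 20 without the filter and 67 by fry. With each library left out in turn, 880 of the 1001 gene results and 79 of the 124 lists passed every time. Where no reason is given, the cause was not tested.

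A 2-fold minimum can only lower a count. In Col-0 it left 6964 genes for scion minus intact, 4924 for rootstock minus intact and 5104 for scion minus rootstock, in dof quadruple 6989 and 4693 for scion and rootstock minus intact, in erf114,115 6373 and 5346, and in anac071,096 6229 and 4729. With loci of chromosome 4 not counted, an alternative chosen after seeing the data that leaves fewer genes to call, dof quadruple minus Col-0 in the scion fell to 181.

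With a replicate block, erf114,115 minus Col-0 in the scion called 301 genes in place of 174 and the erf114,115 scion response difference 25 in place of 10, and the correlation of the dof quadruple and anac071,096 effects in the rootstock was 0.33. The cause was not tested. Deviations of 29 of 36 libraries correlated best with those of their own number (mean r 0.08, against -0.04 with other numbers), and the second component of the deviations was negative for replicate 1 and positive for replicate 3 in all 12 groups. These are hints from the data, not the design, that the numbers share something beyond the 5 comparisons that met the correlation check. For these 5 comparisons the counts without and with the block follow. They were 893 and 1058 for dof quadruple in intact tissue, 727 and 944 in the rootstock, and 6 and 6 for erf114,115 in intact tissue. For erf114,115 scion and rootstock minus intact they were 9790 and 10269, and 8721 and 9191. The block changed none of these by more than 1.5 times. Over all comparisons 997 of the 1001 gene results and 122 of the 124 lists still passed, and the cambium (adjusted p 0.0559) and epidermis and stomata (0.0512) lists of Col-0 rootstock minus intact did not. A further 20 genes and 8 lists passed only with the block.

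In a fit of the compared groups only, which estimates the spread from fewer libraries, counts moved both ways. Rootstock minus intact in erf114,115 called 4702 genes. Against Col-0, dof quadruple called 595 in intact tissue and 605 in the scion, erf114,115 1 in intact tissue and 4 in the rootstock, and anac071,096 3, 179 and 65 in intact tissue, scion and rootstock. Response differences fell to 2 and 3 for erf114,115 in scion and rootstock and 10 for anac071,096 in the rootstock.

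By limma-voom, erf114,115 minus Col-0 in the scion called 353 genes and anac071,096 minus Col-0 120. Response differences fell to 102 for dof quadruple in the rootstock, 5 and 2 for erf114,115 and 3 and 15 for anac071,096 in scion and rootstock. DESeq2 called more: 10, 379 and 188 for erf114,115 minus Col-0 in intact tissue, scion and rootstock, and 15 and 155 for anac071,096 in intact tissue and scion. Its response differences in scion and rootstock were 306 and 296 for dof quadruple, 65 and 35 for erf114,115 and 44 and 103 for anac071,096.

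Over genes called in either mutant in place of all tested genes, the correlations of effects changed. In intact tissue they were 0.24 for dof quadruple with erf114,115, 0.33 with anac071,096 and 0.64 for erf114,115 with anac071,096. In the scion they were 0.01, 0.05 and 0.40 in that order, and in the rootstock 0.28 for dof quadruple with anac071,096 and 0.52 for erf114,115 with anac071,096. Within 100 loci of the targeted genes, fewer loci than 300, the odds ratio of dof quadruple calls was 0.286 (p 0.269), and by construction fewer genes were compared.

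Leaving out a library leaves 2 in an arm, so falls may come from the smaller number of libraries alone, while rises were not tested for a cause. The lowest and highest counts for mutant minus Col-0 were 376 and 614 for dof quadruple in the rootstock, 3 and 5 for erf114,115 in intact tissue, 94 and 142 in the scion and 47 and 111 in the rootstock, and 33 and 55 for anac071,096 in the scion and 84 and 192 in the rootstock. For response differences in scion and rootstock they were 114 and 211, and 114 and 195, in dof quadruple, 10 and 17, and 4 and 18, in erf114,115, and 3 and 6, and 18 and 54, in anac071,096.

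The test of 2 results changed direction. GPT2 in dof quadruple rootstock minus intact was at 4.16, and at -3.98 to 4.91 with single libraries left out, the lowest without dof quadruple rootstock replicate 1, where it no longer passed (adjusted p 0.326). That replicate held all 88 counts of GPT2 in the rootstock, so the fitted -3.98 is no fold, and the intact level was at least 1.24-fold higher. The cytokinin response list in anac071,096 minus Col-0 in the scion had a median of 0.05 and did not pass. With single libraries left out the median was -0.21 to 0.6, the lowest without anac071,096 scion replicate 3, where the list passed downward (adjusted p 0.0493). The cause of the latter was not tested. The medians of 2 passing lists changed sign while the test kept its direction: primary cell wall in the erf114,115 rootstock (-0.06, and 0.04 without Col-0 rootstock replicate 3) and photosynthesis in the anac071,096 scion (0.18, and -0.02 without anac071,096 scion replicate 1, where it no longer passed).

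The filter for low counts left 19476 of 33341 loci, and whether deeper libraries would have counted more was not tested. Of 1.5-fold changes simulated in few genes, 13.4% were recovered (1.49% for response differences), above a minimum mean CPM. Many changes at once were not simulated.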

Other observations

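For the comparisons of 3 libraries with 3, all 10 splits of the 6 libraries were fitted, which are too few for a share under 0.05. Within Col-0 the real splits called 10185, 6339 and 9799 genes for scion minus intact, rootstock minus intact and scion minus rootstock, and the highest other split 0 each time. Within dof quadruple they called 11612 and 8777, within erf114,115 7841 and 4702, and within anac071,096 9149 and 5543 for scion and rootstock minus intact, again with 0 in the highest other split. For dof quadruple minus Col-0 they called 595, 605 and 674 in intact tissue, scion and rootstock, with 0 in the highest other split. For erf114,115 minus Col-0 in the scion the real split called 136 and the highest other 0, and in the rootstock 4 and 1. For anac071,096 minus Col-0 in the scion it called 179 and the highest other 6, and in the rootstock 65 and 27. In each of these comparisons 1 split, the real one, called as many genes.

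In intact tissue of erf114,115 and Col-0, 2 splits called as many genes as the real one. The real split called 1 gene and the highest other 1047. That split set Col-0 replicates 1 and 3 with erf114,115 replicate 1 against the other libraries, so it parted replicates 1 of both genotypes from replicates 2 of both, and points to a structure that follows the replicate numbers. The remaining splits, among them the others that part all 3 numbers as the real one does, called 0. For anac071,096 and Col-0 in intact tissue, 2 splits called as many as the real one, which called 3, and the highest other called 181. It set Col-0 replicates 1 and 2 with anac071,096 replicate 1 against the other libraries, so it parted replicates 1 of both genotypes from replicates 3 of both, and also points to a structure that follows the replicate numbers.

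Of the nuclear calls of dof quadruple against Col-0, 26.9% in intact tissue, 38.7% in the scion and 29.5% in the rootstock lay on chromosome 4 (Fisher's exact p 3e-20, 1.4e-22 and 1.8e-23). Response differences of dof quadruple did not gather there. Their share on chromosome 4 was 17.4% in the scion (0.409) and 18.9% in the rootstock (0.170).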
